A study of Homo sapiens with 6 samples.

How the data were processed

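H3K27ac, the acetylation of lysine 27 of histone H3 that marks active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in LNCaP cells, an androgen-sensitive human prostate cancer line. The cells were stable lines in which a tetracycline-inducible construct expressed V5-tagged FOXA1, a forkhead transcription factor, as the wild-type protein (WT) or with the forkhead-domain substitution D226G or M253K. Per the labels, the cells were kept in medium with 5% CSS, read here as charcoal-stripped serum, which is depleted of steroid hormones. They received doxycycline for 2 days, and libraries were made with a ThruPLEX DNA-seq kit. The 6 samples formed 3 groups of 2 technical replicates.

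Each group had 1 deposited peak list, which the labels of both of its replicates name, so the lists give no value per replicate. The submitters' processing notes name BWA 0.7.2-r351, SAMtools 0.1.18, MACS2 2.0.10.20131216 and the build hg19 (GRCh37), without roles, order or settings. Whether and how the replicates were combined, and whether an input library served as background, is not given in the sources used here. The local rates solved below bear on the second question. Every peak in the 3 deposited lists has a name that begins with H3K27me3, a repressive mark, whereas the labels give H3K27ac. The lists are described here as H3K27ac, following the labels, and the disagreement could not be resolved from the lists.

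Each deposited row gives an interval, a score, a fold enrichment (a ratio of signal to background at the summit), a −log10 p-value, a −log10 q-value and a summit position. These values are the authors' own for each peak and were used in the report to describe, rank or filter peaks within a list. In the closing section they also served to solve for pileups that are compared between lists. The deposited score equalled 10 times the −log10 q-value, rounded down, for nearly all peaks and was not used further. The lowest deposited −log10 q-value was 1.62 in the WT list, 1.47 in the D226G list and 1.48 in the M253K list.

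Peaks on chromosomes 1 to 22 and X were kept, which left out 1520 WT, 1551 D226G and 1841 M253K peaks (2.07%, 1.95% and 1.84%). Lists were compared by overlap of at least 1 bp. The strong peaks of a list were the 20000 with the highest −log10 q-value, ties being ordered by fold enrichment and then position. A strong peak was called absent from another list when it overlapped no peak of any strength there. For sets drawn from both mutant lists, the number of peaks that independent lists would share was computed as n1 × n2 / N, with N the 20000 strong peaks. Shares have exact Clopper-Pearson 95% intervals, and medians of distances have order-statistic intervals. With 1 list per group no test between groups was possible, and the intervals cover counting error only, not differences between cultures or libraries.

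These comparisons, their alternatives and the rule for naming peaks were fixed before the data were examined. The rule took the 10 strong absent peaks with the highest fold enrichment in each direction of each pair, and the same for peaks that were strong in both mutants or lost in both. Merged regions, distances between regions, chromosome ratios, counts in windows of 500 kb and clusters of peaks with gaps of up to 500 kb were added after the lists had been seen. Over chromosomes, Pearson's r and Spearman's rho were tested with 2-sided permutation tests of 100000 resamples, with Benjamini-Hochberg adjustment over 3 relations.

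No hg19 annotation or genome sequence was used here, so peaks are given by position, 1-based on hg19. The planned promoter shares, gene lists and sequence motifs were therefore not analysed here, and neither were the peaks near single genes fixed beforehand.

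For the closing section, the summit pileup (the number of fragments over the summit) and the background rate behind each peak were solved from the deposited fold enrichment and −log10 p-value. The model was fold = (pileup + 1)/(rate + 1), with p the upper Poisson tail. A whole-number pileup gave the deposited −log10 p-value within 0.001 for 71963 of 71963 WT, 78060 of 78061 D226G and 97969 of 97972 M253K peaks. The most frequent rate, 2.04 in WT, 1.94 in D226G and 2.28 in M253K, was taken as the genome-wide background and served as the measure of depth. Of the rates above it and below 6, 100% in each list were whole multiples, within 0.02, of the shortest peak length (197 bp, 193 bp and 204 bp) divided by 10 kb. At any other length tried, from 150 to 330 bp, the share was at most 6.71%, 6.28% and 33.4%. Such steps would arise if background were counted from reads of the ChIP library itself within 10 kb, without an input, in which case fold enrichment is relative to the surrounding acetylation signal. Assuming a mappable genome of 2.7 Gb, which no source used here states, these rates correspond to 28.0 M, 27.1 M and 30.2 M reads. In a test on simulated data, 5000 peaks per list, the pileups were recovered for 100% of peaks. All 200 strong peaks removed from each simulated list were found and 0 others were called absent.

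Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered stricter thresholds, other overlap rules, lists of equal length, other sizes and rankings of the strong set and the joining of nearby peaks.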

Results

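The data comprised 3 lists of H3K27ac peaks from LNCaP prostate cancer cells, 1 each after induction of wild-type FOXA1 (WT), FOXA1 D226G or FOXA1 M253K. FOXA1 is a pioneer factor, a protein that binds and opens closed chromatin, and both substitutions lie in its DNA-binding forkhead domain. The comparisons ask where acetylation differs between cells with mutant and wild-type FOXA1, and between the mutants. All 6 samples were induced, so gain and loss below are relative to the WT list and not to uninduced cells. The labels of both technical replicates of a group name the same list, so no value has a replicate error and no difference below was tested against one. Intervals are 95% Clopper-Pearson unless stated and cover counting error only. The names of all peaks in the lists read H3K27me3 where the labels give H3K27ac, which leaves the identity of the mark resting on the labels. Fold enrichments are the authors' values over a local background, whose library the labels do not name. Read totals per library were not used here.

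The WT list held 71963 peaks, the D226G list 78061 and the M253K list 97972 on chromosomes 1 to 22 and X. The D226G list was thus 8.47% and the M253K list 36.1% longer than the WT list. The covered length was 41.6 Mb in WT, 43.1 Mb in D226G and 58.1 Mb in M253K. The median peak width was similar, at 425 bp, 419 bp and 444 bp. The strong peaks, the 20000 of each list with the highest −log10 q-value, began at a −log10 q-value of 20.2 in WT, 21.7 in D226G and 29.1 in M253K.

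Merging the lists gave 109313 regions, of which 49823 (45.6%) were called in all 3 lists. Another 14812 regions were called in both mutants and not in WT, against 5886 in WT and M253K and 1453 in WT and D226G. Regions called in 1 list numbered 24190 for M253K, 8919 for WT and 4230 for D226G. The order of M253K and WT depended on list length. With 71963 peaks taken from each list, a setting chosen after the data had been seen, 9868 regions were called in M253K alone and 12927 in WT alone. Under that setting, regions shared by both mutants and not WT numbered 10081, above the 3828 of WT with M253K and the 3322 of WT with D226G.

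**Figure D1:**
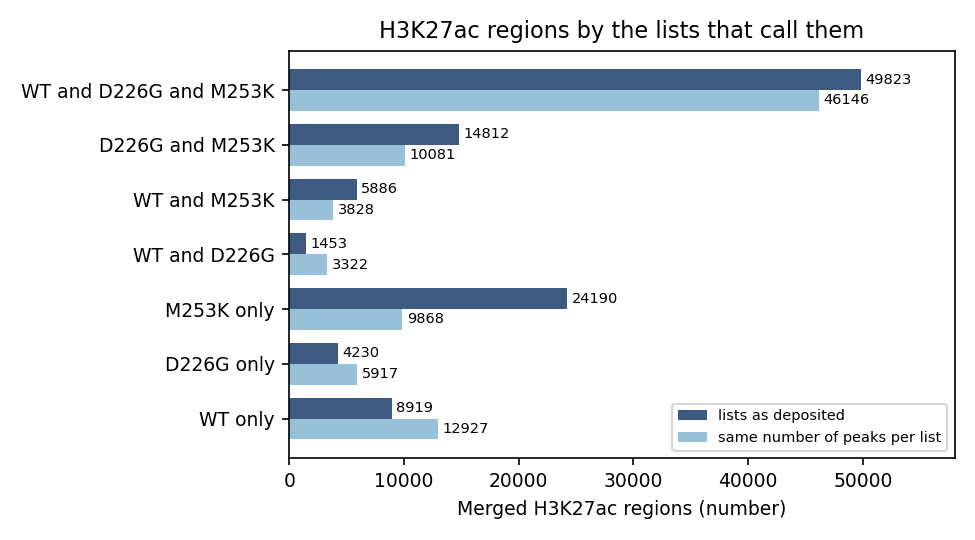
Number of merged H3K27ac regions (horizontal axis) by the lists that call them (vertical axis), for the lists as deposited (dark bars) and with the same number of peaks per list (light bars). Among regions called in exactly 1 pair of lists, those of D226G and M253K were the most numerous in both settings, at 14812 and 10081.

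The first comparison set D226G against WT. Of the 20000 strong D226G peaks, 113 (0.565%, 0.466% to 0.679%) overlapped no WT peak, while 49 of the strong WT peaks (0.245%, 0.181% to 0.324%) overlapped no D226G peak. The absent D226G peak with the highest fold enrichment lay on chromosome 4 at 69885852 to 69886186 (11.6-fold over background). It was followed by peaks on chromosome 15 at 94653729 to 94654060 (11.6-fold) and on chromosome 4 at 106751907 to 106752561 (11.6-fold). All 113 overlapped an M253K peak, and 53 of them a strong one. Since 0 of all 20000 strong D226G peaks lacked an M253K peak, the first of these counts says nothing particular about the 113. In the other direction, the leading WT peaks absent from D226G lay on chromosome 16 at 71235267 to 71235735 (10.6-fold), on chromosome 9 at 87389959 to 87390384 (9.71-fold) and on chromosome 1 at 92877494 to 92877891 (8.99-fold). Of these 49 WT peaks, 23 overlapped an M253K peak and 26 did not. Across all peaks, 73.1% (72.7% to 73.4%) of the D226G list overlapped a WT peak and 77.8% (77.5% to 78.1%) of the WT list overlapped a D226G peak. D226G peaks outside the WT list were narrower than those inside it, with median widths of 264 bp and 526 bp. The counts of strong absent peaks depended on the settings. They became 269 and 142 when 50% of a peak had to be covered, 902 and 429 when ranked by fold enrichment, and 3 and 0 in the top 10000 or 2773 and 2080 in the top 40000. With the other list as long as the shortest they were 113 and 61.

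The comparison of M253K with WT gave the largest number of strong absent peaks among the 6 directions. Here 206 strong M253K peaks (1.03%, 0.895% to 1.18%) overlapped no WT peak, and 41 strong WT peaks (0.205%, 0.147% to 0.278%) overlapped no M253K peak. The leading M253K peaks lay on chromosome 5 at 108340661 to 108341113 (15.6-fold), on chromosome 14 at 31280901 to 31281389 (14.6-fold) and on chromosome 1 at 227456347 to 227456815 (13.7-fold). Peaks on chromosome 11 at 115655717 to 115656189 (13.4-fold), on chromosome 3 at 174520247 to 174520789 (13.3-fold) and on chromosome X at 10437662 to 10438471 (12.8-fold) followed. Of the 206, 204 overlapped a D226G peak and 54 a strong D226G peak. Only 2 of all 20000 strong M253K peaks lacked a D226G peak, so the count of 204 says little about the 206. The WT peaks absent from M253K were led by the chromosome 16 peak that was also absent from D226G. Next came peaks on chromosome 2 at 132324562 to 132325048 (10.3-fold) and on chromosome 20 at 46523455 to 46524132 (8.85-fold), both of which overlapped a D226G peak. Across all peaks, 59.5% (59.2% to 59.8%) of the M253K list overlapped a WT peak, and 85.3% (85.1% to 85.6%) of the WT list overlapped an M253K peak. The M253K share was 71.9% with equal numbers of peaks. The counts of 206 and 41 became 655 and 65 when 50% of a peak had to be covered, 1542 and 222 when ranked by fold enrichment, and 7 and 0 in the top 10000 or 3660 and 1285 in the top 40000. With the other list as long as the shortest they were 206 and 65.

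**Figure D2:**
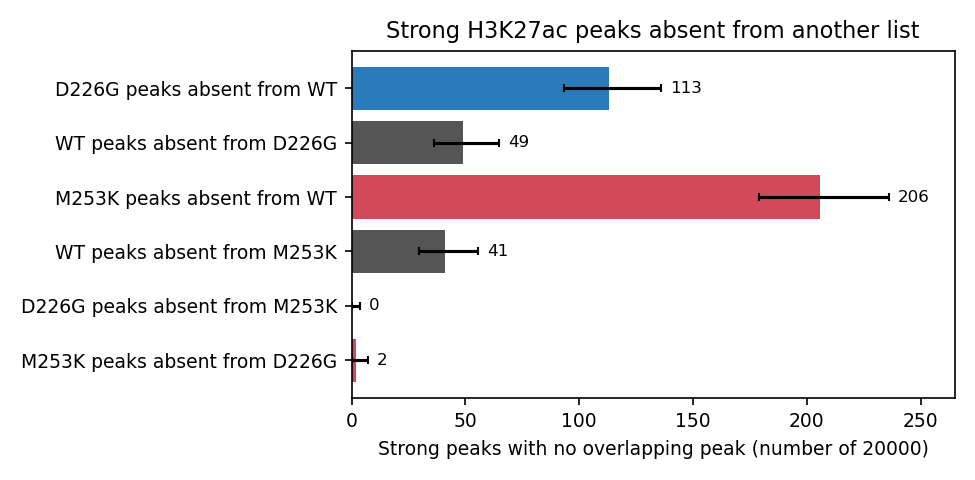
Number of the 20000 strong peaks of one list that overlap no peak of another list (horizontal axis) for the 6 directions (vertical axis), with error bars for the 95% Clopper-Pearson interval of counting error. The mutant peaks absent from WT number 113 and 206, and those absent from the other mutant 0 and 2.

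Peaks that were strong in both mutants and absent from WT numbered 53, where independent lists would share 1.16. The value of 1.16 is no fair expectation, since the same WT list enters both comparisons. All 20000 strong D226G peaks overlapped an M253K peak, and so did the 113 of them that WT lacks. No conclusion is drawn from the excess. The count of 53 became 1 in the top 10000, 1635 in the top 40000 and 422 when ranked by fold enrichment. It stayed at 53 with every list as long as the shortest. The set was led by peaks on chromosome 4 at 106751907 to 106752561, with 11.6-fold enrichment in the D226G list and 10.16-fold in the M253K list, and on chromosome 3 at 177820841 to 177821280, with 11.4-fold and 9.66-fold. Peaks on chromosome 5 at 108340659 to 108341075 (11.4-fold and 15.6-fold), chromosome 3 at 166699313 to 166699650 (11.2-fold and 11.9-fold) and chromosome 10 at 45135883 to 45136343 (11.1-fold and 9.52-fold) came next. Those on chromosome 6 at 151512375 to 151513003 (10.99-fold and 10.4-fold) and chromosome 11 at 100464986 to 100465408 (10.9-fold and 11.6-fold) followed. Chromosome 3 held 11 of the 53 and chromosome 1 held 7, where the whole D226G list of 78061 peaks had 5055 and 7696 there. Several lay close together, a feature singled out after the values were seen. Chromosome 3 had 4 of these peaks between 71214998 and 71604824, 3 between 177714838 and 178110985 and 2 between 138456939 and 138479306, and chromosome 15 had 2 between 43262775 and 43300892. A WT peak lay within 1000 bp of 11 of the 53.

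Strong WT peaks absent from both mutants numbered 26, where independent lists would share 0.10. That value leaves out the WT list common to both comparisons and the overlap between the mutant lists, so no conclusion is drawn from it. The count of 26 became 0 in the top 10000, 995 in the top 40000 and 174 when ranked by fold enrichment. It rose to 38 with every list as long as the shortest. The 26 were led by the chromosome 16 peak at 71235267 to 71235735 (10.6-fold) and by peaks on chromosome 5 at 141766208 to 141767147 (8.60-fold) and chromosome 3 at 42225980 to 42226716 (7.98-fold). Peaks on chromosome 12 at 123518740 to 123520379 (7.68-fold), chromosome 11 at 16819199 to 16819987 (7.68-fold) and chromosome 5 at 131794549 to 131795373 (7.23-fold) followed. A further peak on chromosome 12 at 123616297 to 123617144 (7.06-fold) lay near the first on that chromosome, the pair spanning 98.4 kb.

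Between the mutants, 0 of the 20000 strong D226G peaks lacked an M253K peak, which allows a share of up to 0.015% at 3 counts, with an upper Clopper-Pearson bound of 0.0184%. In the other direction 2 strong M253K peaks lacked a D226G peak. They lay on chromosome 9 at 102873514 to 102873917 (11.6-fold) and on chromosome 14 at 32788341 to 32788726 (9.25-fold), and neither overlapped a WT peak. These counts of 0 and 2 became 2 and 76 when 50% of a peak had to be covered, 39 and 296 when ranked by fold enrichment, and 136 and 569 in the top 40000. Of all D226G peaks, 92.4% (92.2% to 92.6%) overlapped an M253K peak. Of all M253K peaks, 68.7% (68.4% to 69.0%) overlapped a D226G peak. The M253K peaks outside the D226G list, 30703 in number, had a median width of 274 bp, against 591 bp for those inside it. With equal numbers of peaks the shares were 86.8% and 80.6%. The D226G list overlapped the M253K list more often than the WT list in each of the 4 other settings tried.

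Regions called in M253K alone lay farther from regions called in all 3 lists than those called in WT or D226G alone. The median distance was 15.5 kb (15.1 to 15.9 kb) for M253K alone, 9.14 kb (8.90 to 9.43 kb) for WT alone and 9.47 kb (8.86 to 10.02 kb) for D226G alone. It was 10.4 kb (10.1 to 10.8 kb) for regions called in both mutants. With equal numbers of peaks the medians were 14.7 kb for M253K alone, 13.3 kb for D226G alone and 10.15 kb for WT alone. The contrast between the mutants thus depended largely on list length. By chromosome, the ratio of M253K to WT peaks ranged from 1.04 on chromosome 19 to 1.61 on chromosomes 4 and 13. The D226G ratio was highest on chromosome 4 (1.21) and below 1 on chromosomes 16 (0.969), 17 (0.983), 19 (0.993), 20 (0.980) and 22 (0.975). Over the 23 chromosomes the M253K ratio fell with the density of regions called in all 3 lists (r = −0.88, rho = −0.90, permutation p = 1e-05 for each, adjusted p = 1e-05). The D226G ratio did so too (r = −0.82, rho = −0.85), as did the ratio of M253K to D226G peaks (r = −0.90, rho = −0.92), with the same permutation p. This p is the smallest that 100000 resamples can give. Without chromosomes 19 and 22 the r values were −0.83, −0.78 and −0.84. Chromosomes of 1 list per group are not replicates of the groups. The density was counted from the same lists as the ratios, a link that permutation ignores, so this p is no test of an independent relation.

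**Figure D3:**
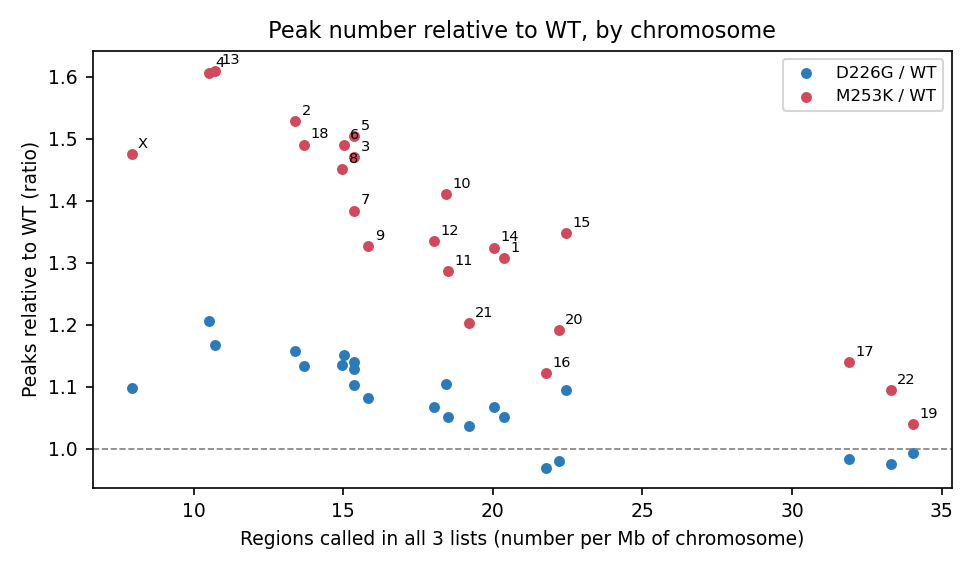
Ratio of the number of peaks in each mutant list to that in the WT list (vertical axis) against the number of regions called in all 3 lists per Mb of chromosome (horizontal axis), 1 point per chromosome for D226G (blue) and M253K (red, with chromosome names). The M253K ratio runs from 1.61 on chromosomes 4 and 13 to 1.04 on chromosome 19, and the dashed line marks a ratio of 1.

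Single windows of 500 kb were also compared, among the 5397 that held a peak. Extremes of so many small counts differ more than whole chromosomes through counting error alone, and no expected extreme was computed. The windows were ranked by the smaller of the differences of both mutants from WT, scaled to list length and divided by its counting error. First in gain was chromosome 6 from 20.5 to 21 Mb, with 9 peaks in WT, 32 in D226G and 33 in M253K. Windows on chromosome 12 from 62.5 to 63.0 Mb (7, 23 and 29 peaks) and on chromosome 2 from 172.5 to 173.0 Mb (16, 37 and 45 peaks) followed. First in loss was chromosome 2 from 3.0 to 3.5 Mb, with 39 peaks in WT, 19 in D226G and 25 in M253K. Next in loss by that measure were chromosome 21 from 17.5 to 18 Mb (103, 77 and 89 peaks) and chromosome 20 from 33.0 to 33.5 Mb (51, 32 and 35 peaks). Windows were ranked after the lists had been seen, and 3 of these 6 were also among the leading windows of 1000 kb.

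**Figure D4:**
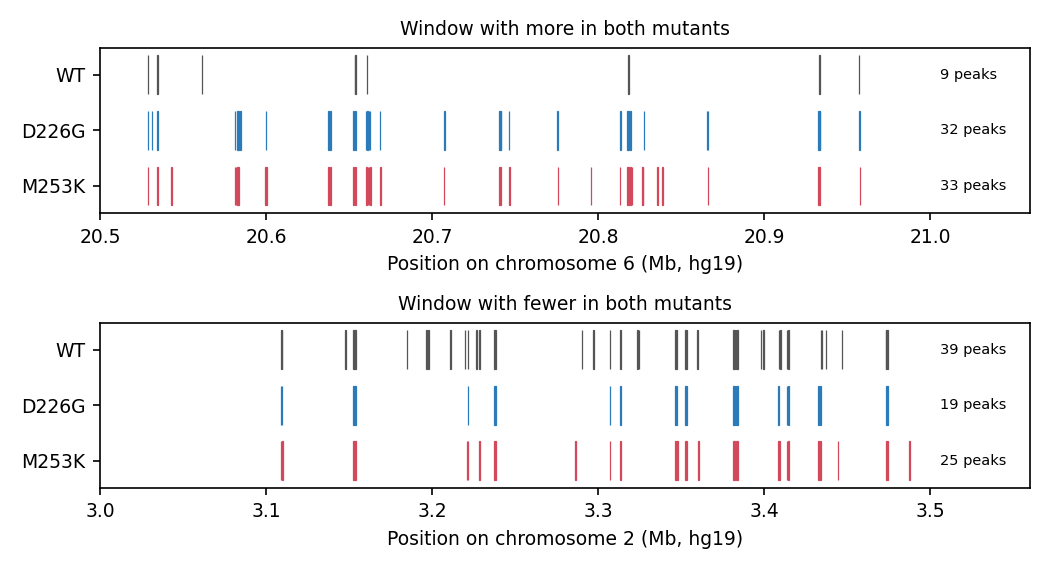
Positions of H3K27ac peaks (vertical bars, horizontal axis in Mb on hg19) in the WT, D226G and M253K lists in the 500 kb windows ranked first in shared gain (chromosome 6) and shared loss (chromosome 2). The chromosome 6 window holds 9, 32 and 33 peaks and the chromosome 2 window 39, 19 and 25.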

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

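Lists of equal length in the comparison of merged regions and distances, windows of 1000 kb and the settings for pileups were chosen after the data had been seen. No paired analysis was possible because each group had 1 list, which the labels of both technical replicates name, and for the same reason no replicate could be left out. The alternatives for promoter shares, gene lists and sequence motifs were not run, since no hg19 annotation or sequence was used here. The number of peaks kept its order, WT below D226G below M253K, in all 3 alternatives. The lists held 57109, 62822 and 76941 peaks at a −log10 q-value of at least 5. They held 50266, 57762 and 67587 at a fold enrichment of at least 4, and 51965, 54041 and 68684 with peaks within 1000 bp joined. Shares of peaks overlapped are given for D226G by WT, WT by D226G, M253K by WT, WT by M253K, D226G by M253K and M253K by D226G, in that order. With 50% of the peak covered they were 68.6%, 73.7%, 52.7%, 82.5%, 90.2% and 62.0%. With the summit inside a peak they were 69.6%, 74.1%, 55.9%, 82.4%, 89.8% and 64.8%. At a −log10 q-value of at least 5 they were 74.1%, 79.9%, 61.9%, 86.8%, 92.8% and 71.4%, and with lists of equal length 75.8%, 75.03%, 71.9%, 77.1%, 86.8% and 80.6%. Each mutant list overlapped the other mutant list more often than WT in all 4. Strong absent peaks, for the same directions, numbered 269, 142, 655, 65, 2 and 76 when 50% of the peak had to be covered. They numbered 3, 0, 7, 0, 0 and 0 in the top 10000 and 2773, 2080, 3660, 1285, 136 and 569 in the top 40000. Ranking by fold enrichment gave 902, 429, 1542, 222, 39 and 296. With the other list as long as the shortest they numbered 113, 61, 206, 65, 1 and 4. With the other list extended by 1000 bp, WT peaks absent from M253K numbered 26 and M253K peaks absent from D226G 1. More strong mutant peaks were absent from WT than strong WT peaks from the mutant in all 6 alternatives, for both mutants, though in the top 10000 this rests on counts of 3 and 7. Peaks strong in both mutants and absent from WT numbered 1 in the top 10000, 1635 in the top 40000 and 422 when ranked by fold enrichment. For WT peaks absent from both mutants these were 0, 995 and 174. With every list as long as the shortest, the counts were 53 strong in both mutants and absent from WT, and 38 strong in WT and absent from both. The margin between them was thus smaller than that of 53 over 26. Lists of equal length moved the regions called in M253K alone to 9868, below the 12927 of WT alone, and those of WT with D226G to 3322 and of WT with M253K to 3828. This setting shortened the D226G and M253K lists together. For these and the other changes the cause was not tested. The median distances to regions called in all 3 lists became 14.7 kb for M253K alone, 10.15 kb for WT alone, 13.3 kb for D226G alone and 11.3 kb for both mutants. With the highest pileup at 100 or more, the regions at least 2-fold higher and lower in both mutants numbered 206 and 10. Median scaling and saturation gave 694 and 946 higher and 74 and 72 lower. Peaks near the calling limit, where the lowest pileup was 8 fragments, are the ones whose absence from a list says least.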

Other observations

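The tests for a higher yield, sampling noise, an atypical WT library and AT-rich fragments, the interval for copy number, the ratio that copy number would need and all counts of pileups were chosen after the result was seen. The thinning test was set before it was run, with the background rates already known. Summit pileups solved from the authors' values allow regions called in all 3 lists to be compared by level, relative to each list's background rate. Among 22662 such regions with a pileup of at least 60 in some list, 771 were at least 2-fold higher in both mutants than in WT and 58 at least 2-fold lower in both. None, 0, went opposite ways by that amount. The simulated lists without any effect, described below, also gave 0, and both ratios share the WT list, so this 0 says little. With a pileup of at least 100 the numbers were 206 and 10. Regions were ranked by the mean log2 ratio of both mutants to WT. The first in gain lay on chromosome 11 at 93075478 to 93076519, with pileups of 12 in WT, 72 in D226G and 113 in M253K. Relative to background it was 6.33-fold higher in D226G (95% interval for counting error 3.41 to 12.8) and 8.44-fold higher in M253K (4.65 to 16.8). Regions on chromosome 6 at 113480885 to 113481641 (10, 54 and 78) and chromosome 1 at 92909509 to 92910247 (15, 80 and 115) followed. So did chromosome 3 at 138470223 to 138470905 (14, 74 and 94), which lies between the strong peaks of both mutants at 138456939 to 138479306 that WT lacks. The first in loss were on chromosome 6 at 43868362 to 43869478 (73, 16 and 10), chromosome 12 at 57810202 to 57810969 (86, 13 and 23) and chromosome 7 at 138981098 to 138981755 (64, 14 and 12).

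The mutants differed less from each other. M253K was at least 2-fold above D226G in 47 regions, led by chromosome 6 at 109380328 to 109381335 with pileups of 24 in WT, 23 in D226G and 78 in M253K. D226G was at least 2-fold above M253K in 4 regions, led by chromosome 9 at 79413532 to 79414349 (122, 131 and 56), where M253K stood at 0.363 of D226G (0.261 to 0.50). These counts of 47 and 4 became 19 and 7 when scaled by the median of shared regions, 2 and 1 with a pileup of at least 100 and 87 and 4 after correction for saturation. The SD of the log2 ratio over regions was 0.24 between the mutants, where Poisson noise alone gave 0.21, against 0.42 for D226G over WT and 0.49 for M253K over WT. Both ratios to WT correlated over regions (r = 0.87), which are not independent replicates. Simulated lists without any effect, which share the WT list in the same way, gave r = 0.51, and the covariance was 0.177 against 0.0238. They held a mean of 0.25 regions at least 2-fold higher in both mutants and 0 lower, with Poisson noise as their only spread. Between the mutants they held a mean of 2 regions with M253K at least 2-fold above D226G and 0.8 the other way, beside the 47 and 4 above. The count of 4 is thus small enough that little rests on it.

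The M253K list was longer than the WT list, and its background rate was 1.12 times as high. Library depth as the whole cause is argued against by thinning: at a −log10 p-value of at least 10, M253K had 58568 peaks and WT 42108, and 76.0% of that excess was left after the M253K pileups were thinned to the WT rate in 20 draws. A higher yield of the precipitation in all regions stays open. Corrected for saturation, the median log2 ratio of M253K to WT was 0.0302 in the eighth of shared regions with the highest pileup and 0.222 in the others. Without the correction these medians were −0.0134 and 0.197. The SD over single regions of that eighth was 0.269 with the correction and 0.201 without, and it is not an error of the median. The highest eighth thus gained less than the others in both settings, but 1 list per group gives these medians no error between libraries. From the fourth eighth upward the corrected median fell with pileup, from 0.354 through 0.318, 0.186 and 0.0844. It was 0.109 in the lowest eighth, where the need for a call in all 3 lists may limit the ratio, which was not tested. An effect of M253K stays open as well, since 1 list per group cannot separate it from a difference between libraries.

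For the 53 strong peaks of both mutants that WT lacks, copy number of the region as the only cause of the whole set is argued against. Lifting a pileup that WT would leave uncalled to the mutant pileup needs a log2 ratio of at least 1.15 in M253K (median 2.00) and 1.17 in D226G (median 1.95). The WT local rate was taken as the scaled mutant rate. Shared regions within 1000 kb had medians of at most 1.06 and 0.82, and 0 of 53 neighbourhoods reached the need even at the upper 95% bound of their median. The smallest gap was 0.149, in M253K on chromosome 3 at 71214998 to 71215574. The needed ratios carry no counting error, and the choice of peaks strong in both mutants and uncalled in WT raises them. A shared region must have a WT call, which may limit its ratio. The smallest gaps are therefore not decided, and gains narrower than a neighbourhood were not tested. Poisson draws at the WT depth lost a mean of 0 peaks, but the choice of strong peaks fixes that outcome. Even with the highest loss probability of any peak given to all D226G peaks strong in both mutants, 0.0106 would be lost. The draws also leave out the spread between libraries, so they do not decide on sampling noise. The neighbouring regions, each counted once, stood 0.0825 above all shared regions in the median log2 ratio of M253K to WT. A bootstrap over the 53 peaks gave an interval of 0.0275 to 0.204. It counted regions near several peaks repeatedly and treated clustered peaks as independent, so the interval is only rough. Of the 53 neighbourhoods, 8 stood at least 0.5 above, among them all 4 of the chromosome 3 cluster at 71214998 to 71604824. Those 4 had medians of 0.93 to 1.06 in M253K and 0.72 to 0.82 in D226G, against 0.14 and 0.02 over all shared regions. The cluster at 177714838 to 178110985 had 0.36 to 0.58 and 0.29 to 0.42. A smaller contribution of copy number therefore stays open. Peaks that moved or joined remain open for the 11 of the 53 (20.8%) with a WT peak within 1000 bp, while the other 42 had none within that distance. An atypical WT library cannot be told apart from an effect of both mutants, because the covariance of 0.177 between the ratios rests on the same WT list.

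The mutant excess was larger on chromosomes with few shared regions (r = −0.88 for M253K, with the density counted from the same lists). Regions called in M253K alone lay farther from shared ones, though with lists of equal length those of D226G alone came close (14.7 kb and 13.3 kb). A bias of the libraries towards AT-rich fragments may give this pattern, as may new acetylation far from existing active regions. These explanations cannot be told apart here, because no genome sequence was used to measure GC content. How closely the density of shared regions follows GC content is therefore unknown here, and a close relation would leave both explanations with the same pattern. The chromosome ratios were not recomputed with lists of equal length, so the part of list length in this pattern was not tested.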
